A study of Arabidopsis thaliana with 14 samples.

How the data were processed

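Leaf RNA of 1-month-old Arabidopsis thaliana plants was measured on 14 ATH1 arrays, 1 array per sample, each labelled with biotin from 250 ng of total RNA. The labels gave 5 groups, which were wild-type Col-0 plants with water (3 arrays) and after 14 days of drought (3 arrays), plants of the line camta5-a with water (3 arrays) and after drought (3 arrays), and the CAMTA5 overexpression line OX-5 after drought (2 arrays). A watered OX-5 group was not analysed here. Array groups and replicate numbers came from the sample titles. For camta5 water replicate 1 the genotype entry read wild type, against its title and source name. That array was grouped by its title, and counting it as Col-0 water was tried as an alternative. The labels called the replicates biological but did not say whether they came from separate plants or pots, so p-values measure only the spread between these samples.

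The deposited values were linear MAS5 signal intensities, made by the authors with Affymetrix Expression Console per the submitters' processing notes, with no version given in the sources used here. Computed from the values, each array had been scaled so that its mean, with 2% of probe sets trimmed at each end, was 500. Detection calls, scanner files and scan batches were not used here. MAS5 values near the floor are noisy, and a probe set's level was not set against that of another probe set. Arrays have no read depth, and their number limits the precision. No pair of arrays shared more than 2 identical values among the 22810 probe sets.

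Gene names came from the platform annotation given for these probes, with symbols updated through the Entrez number from a RefSeq table of assembly TAIR10.1. Of 22810 probe sets, 64 were controls, 13513 named 1 gene, 503 named several and 8794, the controls included, had no gene in that annotation and are unnamed here. Of the 1-gene probe sets, 13436 were matched to the RefSeq table and 1579 carried a symbol other than the locus number. No coordinates are printed, since the build behind the probe sets is not given in the sources used here.

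Values were taken as log2(value + 16), and the fold changes are on that scale, which understates the change of low genes. A probe set was tested where it exceeded the array's 40th percentile on at least 2 arrays, which kept 15646 probe sets and left out 7100. The 64 control probe sets were left out. All 14 arrays entered a limma fit (limma 3.58.1, R 4.3.3) with 1 mean per group and no covariates, moderated with a trend, so that the 5 groups shared 1 estimate of the spread. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method within each of 7 comparisons, and a call was an adjusted p under 0.05. Each adjusted p below is from limma or, for gene lists, from limma's camera.

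Before the data were examined, 25 gene lists with 369 entries were fixed, together with the tests, the alternatives and the rule for naming genes. Only 53 entries had a probe set naming that gene alone, and 3 entries were dropped because name and locus did not match. For 8 lists no member was measured, and 6 lists had the 3 measured members that a test needed. A gene with several probe sets was represented by the one with the highest mean. The background of the list tests was the named genes, with a preset correlation of 0.01, and adjustment was over the 6 lists within a comparison. After the annotation was opened, 26 families were formed from the gene symbols, and 25 of them could be tested and were adjusted together. The rule named, in each comparison, CAMTA5, the 8 largest rises and the 8 largest falls among called genes with a symbol whose arrays did not overlap between the groups, and the 2 called members with the largest change from each of the 6 lists with the smallest p. Where no probe set was called, the 5 genes with the smallest p were named by their values alone.

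The procedures were tested on simulated data with the real means and spreads of 15646 probe sets, of which 200 were changed. For drought against water in Col-0, 66% of the probe sets changed by a log2 size of 1 were recovered and 86% of those changed by 2. For OX5 against Col-0 in drought these shares were 42% and 98%, and for the difference of the drought responses 20% and 72%. Of the calls made for these 3 comparisons, 7.25%, 3.97% and 4.04% were unchanged probe sets. The simulated noise was independent between probe sets and had the same spread in every group. The real data gave 4277, 7308 and 0 calls in these comparisons, so the simulated shares do not carry over to them directly.

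Alternatives were an offset of 1 or 64, no filter, a filter at the 60th percentile, quantile normalization, centring on the median, moderation without trend or with robust estimates, array weights, only the arrays of the groups compared, the replicate number as a block, stricter thresholds, leaving out each array in turn, and the other grouping of the array with conflicting labels. For lists, an estimated correlation, fry and the mean over the probe sets of a gene were also tried. The fit without the OX5 arrays, the families (also with each array left out), the comparison of OX5 with watered Col-0, and the estimated correlation and fry for the flavonoid list with each array left out or after scaling were added after seeing the data.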

Results

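The series measured transcript levels in leaves of Arabidopsis plants that were watered or had been left dry for 14 days. CAMTA5 is a calmodulin-binding transcription activator, a calcium-linked regulator of transcription, and the series title links its overexpression to drought tolerance. Col-0 is the wild type, camta5-a a mutant line of the gene and OX-5 (written OX5 here) a line meant to overexpress it. Groups held 3 arrays each, except for OX5 in drought with 2. Within a group of 3, arrays correlated with a Spearman coefficient of 0.942 to 0.956 across probe sets. The OX5 arrays stood apart from the other 12. Their coefficients with those arrays were 0.805 to 0.865, against 0.896 to 0.960 among the other 12, and 0.903 between both OX5 arrays.

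CAMTA5 (AT4G16150) was not lower in the arrays labelled camta5. Its signal was 149 ± 32.5 (SD, n = 3) in Col-0 with water and 172 ± 18.5 (n = 3) in camta5 with water, and 198 ± 46.0 (n = 3) in Col-0 and 285 ± 20.6 (n = 3) in camta5 after drought. OX5 had 346 ± 79.2 (n = 2), a log2 difference of 0.76 ± 0.25 (SE) from Col-0 in drought with an adjusted p of 0.0198. That call ended without Col-0 drought replicate 2 (0.57, adjusted p = 0.0783), without OX5 drought replicate 1 (0.54, adjusted p = 0.172) and in a fit of these 5 arrays alone (adjusted p = 0.0717). Against camta5 in drought the OX5 difference was 0.25 ± 0.25, with an adjusted p of 0.435. Between camta5 and Col-0 the log2 differences were 0.21 ± 0.22 with water (adjusted p = 0.957) and 0.51 ± 0.22 in drought (adjusted p = 0.291). Where the probe set lies relative to the lesion of the mutant line is not given in the sources used here, so this level does not check the label. OX5 replicate 2, at 290, lay within the range of the camta5 drought arrays (265 to 306), so the level does not settle the overexpression either. Below, camta5 and OX5 mean the arrays with those labels, and each direction given for them rests on the label.

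**Figure D1:**
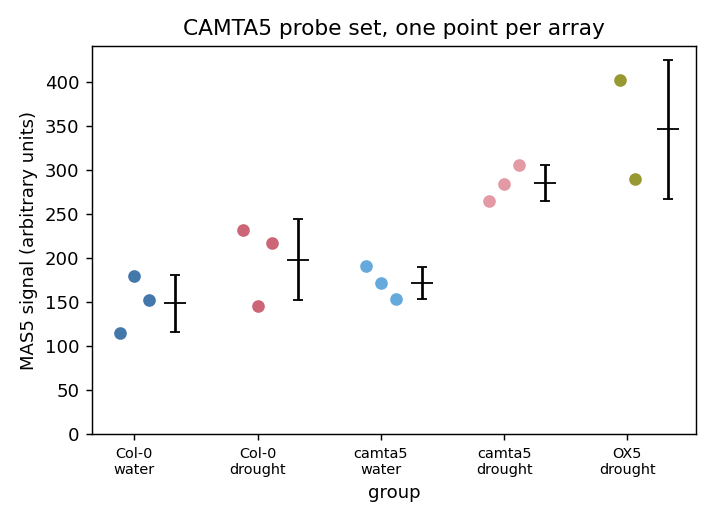
MAS5 signal of the CAMTA5 probe set (arbitrary units, linear axis) in the 5 groups, 1 point per array, with the group mean and SD as a dash and bar. The camta5 drought arrays had a mean of 285 and the Col-0 drought arrays a mean of 198.

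Drought in Col-0 raised the dehydration-protection genes LEA4-5 and LTI30 and the anthocyanin gene DFR, and lowered the measured genes of a fixed list of cell wall loosening. LEA4-5 (AT5G06760), a late embryogenesis abundant protein, rose by 4.50 ± 0.69 on the log2 scale (adjusted p = 0.000487), from 153 ± 54.5 to 4943 ± 3728 (SD, n = 3 each). The dehydrin gene LTI30 (AT3G50970) rose by 4.11 ± 0.76. Of the 6 measured genes of the fixed dehydration list, only these 2 were called higher and 1 was lower. That list was not shifted (camera, adjusted p = 0.644). DFR (AT5G42800), which encodes the dihydroflavonol reductase of the anthocyanin pathway, rose by 5.76 ± 0.72, from 4.52 ± 1.86 to 2307 ± 3169, and the 3 drought arrays had signals of 352, 606 and 5963. Each SE of a log2 difference comes from the spread shared by all 5 groups. For DFR it does not show the wider spread of these 3 arrays. All 7 measured members of the fixed list of expansins and xyloglucan endotransglucosylases, proteins that loosen the wall of growing cells, fell. In the wider families formed after the annotation was opened, 5 of 11 expansin genes fell and 1 rose, and 3 of 5 xyloglucan endotransglucosylase genes fell. EXPA8 (AT2G40610) fell by 3.85 ± 0.60 and XTH19 (AT4G30290) by 3.34 ± 0.40. Leaving out 1 drought array moved some folds by over 1.5 times with the call kept. Without replicate 1 the log2 differences were 5.35 for LEA4-5, 5.14 for LTI30, 6.56 for DFR and -4.61 for EXPA8, without replicate 2 they were 3.89 for LEA4-5, 2.97 for LTI30 and -3.17 for EXPA8, and without replicate 3 that of DFR was 4.55.

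Of the 15646 probe sets tested, 2441 were higher and 1836 lower after drought in Col-0. Among changes of at least 2-fold the balance turned to 896 higher and 1049 lower, and with each array centred on its median 2092 were higher and 2023 lower. Further large rises were those of DI21 (AT4G15910, log2 difference 5.35 ± 0.64), the senescence-associated sugar transporter gene SAG29 (AT5G13170, 4.90 ± 0.37), the linker histone gene HIS1-3 (AT2G18050, 3.57 ± 0.25), UF3GT (AT5G54060, a glycosyltransferase of the anthocyanin pathway, 3.47 ± 0.65) and the methionine gamma-lyase gene MGL (AT1G64660, 3.09 ± 0.33). Large falls were those of the thionin gene THI2.2 (AT5G36910, -4.37 ± 0.39), SP1L4 (AT5G15600, -3.77 ± 0.47), the defensin gene PDF1.2b (AT2G26020, -3.75 ± 0.78), EXPA16 (AT3G55500, -3.47 ± 0.47), TBL45 (AT2G30010, -3.42 ± 0.44) and MSRB6 (AT4G04840, a methionine sulfoxide reductase, -3.40 ± 0.34). For each of these genes every drought array lay on 1 side of every water array, as the naming rule required. Of the 15646 probe sets, 6975 did so. The differences without Col-0 drought replicate 1 were 6.18 for DI21, 4.07 for UF3GT, -4.41 for SP1L4 and -4.05 for TBL45, without replicate 2 that of DI21 was 4.42, without replicate 3 that of UF3GT was 2.50, and without Col-0 water replicate 1 that of PDF1.2b was -4.54, all called. CAMTA5 itself had a log2 difference of 0.38 ± 0.22 (adjusted p = 0.226), and its relative CAMTA4 (AT1G67310) rose by 0.73 ± 0.17 (adjusted p = 0.00511). Without Col-0 drought replicate 2, the count of 4277 changed probe sets was 2601 (1464 higher and 1137 lower).

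The cell wall list was shifted down (median log2 difference -2.13, adjusted p = 6.27e-06, and adjusted p = 0.0497 with an estimated correlation). All 7 of its members were also called when adjusted over the list alone. Of 4 flavonoid and anthocyanin genes measured, 3 rose (DFR, UF3GT and UGT75C1), 3 also adjusted over the list alone, with a list median of 3.25 (adjusted p = 0.0241, and adjusted p = 0.260 with an estimated correlation). Without Col-0 water replicate 3 the list's adjusted p was 0.060, and without Col-0 drought replicate 3 its median was 2.29. Of 8 photosynthesis genes, 4 fell (7 adjusted over the list alone), with PSBY (AT1G67740, a photosystem II subunit) at -1.36 ± 0.23 and PSAN (AT5G64040, photosystem I) at -0.83 ± 0.19. That list's median was -0.46 (adjusted p = 0.000627, adjusted p = 0.260 with an estimated correlation and 0.0802 after quantile normalization, which left 2 members lower). Dehydration-protective genes went both ways, with 2 of 6 higher and 1 lower, COR15B at -1.94, in both adjustments, and the list was not shifted (adjusted p = 0.644). The senescence list (1 of 3 higher, SAG29, adjusted p = 0.644) and the CAMTA family (1 of 3 higher, adjusted p = 0.164) were not shifted either. The senescence median was -0.46 while its mean was 1.15, since WRKY6 and WRKY53 lay below 0.

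Drought in the camta5 plants changed many of the genes changed in Col-0. SAG29 rose by 4.33 ± 0.37, DI21 by 4.26 ± 0.64, LEA4-5 from 136 ± 66.4 to 3226 ± 2367 (n = 3 each, adjusted p = 0.00227), MGL by 3.14 ± 0.33 and HIS1-3 by 3.10 ± 0.25. LTI30 rose by 2.60 ± 0.76, the wax regulator gene SHN3 (AT5G25390) by 2.07 ± 0.37 and the sugar transporter gene SWEET4 (AT3G28007) by 2.01 ± 0.31. THI2.2 fell by 3.73 ± 0.39, the cytokinin response regulator gene ARR15 (AT1G74890) by 3.62 ± 0.44, XTH19 by 3.60 ± 0.40, SP1L4 by 2.64 ± 0.47 and MSRB6 by 2.50 ± 0.34. None of the 4 anthocyanin genes was called, and DFR was at 47.5 ± 2.14 (n = 3) after drought.

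In camta5, 1357 probe sets were higher and 1190 lower after drought. The balance turned to 1109 higher and 1183 lower after quantile normalization and to 1189 and 1310 with each array centred on its median. Among changes of at least 2-fold, 494 were higher and 596 lower. The plastid genes psbB and petN fell by 2.46 ± 0.54 and 2.41 ± 0.34 and CHIL (AT5G05270, chalcone isomerase-like) by 2.34 ± 0.61. CAMTA5 was 0.68 ± 0.22 higher (adjusted p = 0.0482) and CAMTA6 (AT3G16940) 0.60 ± 0.19 higher (adjusted p = 0.0430). The CAMTA5 call ended when any 1 of the 6 camta5 arrays was left out, with adjusted p of 0.0597 (drought replicate 1) to 0.150 (water replicate 3), and without Col-0 water replicate 2 or 3 or Col-0 drought replicate 3, with 0.050 to 0.0619. Of 7 cell wall genes, 4 fell (7 adjusted over the list alone), EXPA8 by 2.26 ± 0.60, with a list median of -1.56 (adjusted p = 1.31e-05, and adjusted p = 0.0585 with an estimated correlation). Of 8 photosynthesis genes, 4 fell (6 adjusted over the list alone), PSBY by 0.98 ± 0.23 and PSAN by 0.79 ± 0.19, with a list median of -0.65 (adjusted p = 0.000114, adjusted p = 0.175 with an estimated correlation and 0.0543 after quantile normalization, which left 1 member lower). The dehydration list (3 higher, 1 lower), the senescence list (1 higher), the CAMTA family (2 higher) and the flavonoid list were not shifted, with adjusted p of 0.318, 0.318, 0.116 and 0.831. Other settings also ended calls, with adjusted p of 0.0504 to 0.144. These were an offset of 1 (CAMTA5 and EXPA8), no filter (CAMTA5 and CAMTA6), quantile normalization (CAMTA5, CAMTA6 and PSAN), centring on the median, only the compared arrays or no OX5 arrays (CAMTA6 each), moderation without trend (LTI30 and CAMTA6) or with robust estimates (LTI30), and water replicate 1 counted as Col-0 (CAMTA5, CAMTA6 and LTI30). The replicate number as a block ended those of CAMTA5 (0.0665) and CAMTA6 (0.0589). Leaving out 1 array also ended calls of named genes. Without camta5 drought replicate 1, psbB was at -3.34 and the rise of LEA4-5 was 4.92 on the log2 scale, each over 1.5 times its fold with all arrays. LTI30 (adjusted p up to 0.0992) and CHIL (up to 0.0811) lost theirs without any 1 of the camta5 arrays except drought replicate 1. CAMTA6 (up to 0.176) lost it without camta5 water replicate 1 or 2 or drought replicate 2 or 3, and through the shared spread without Col-0 water replicate 2 or 3, Col-0 drought replicate 3 or either OX5 array (0.051 to 0.0562). The same happened to EXPA8 (up to 0.083) without camta5 water replicate 2 or 3 or drought replicate 2 or 3, and to PSBY (0.0675) and PSAN (0.0574) without camta5 drought replicate 2. The count of 2547 was 1333 without camta5 water replicate 1 (722 higher and 611 lower), 1311 without water replicate 3 (703 and 608), 1121 without drought replicate 2 (577 and 544), 1509 without drought replicate 3 (839 and 670) and 1445 with water replicate 1 counted as Col-0 (769 and 676). Without water replicate 2 the 1190 lower probe sets were 708.

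The drought responses of camta5 and Col-0 ran together across probe sets, which are not independent replicates. Between the log2 differences, which share no arrays, Pearson's r was 0.80, and it was 0.00396 in simulated groups with no change. Both responses called 1027 probe sets higher, against 211.7 from independent lists, and 879 lower, against 139.6. No probe set was called in opposite directions. Of the 2441 probe sets that rose in Col-0, 96.9% had the same sign in camta5, with medians of 0.87 in Col-0 and 0.59 in camta5. This set was chosen by its Col-0 calls, which can raise the Col-0 median, so the medians do not compare the sizes of the responses. A slope of the camta5 response on the Col-0 response, corrected for the error in the latter, was 0.78. Its error across arrays was not computed.

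No single probe set differed between the 2 drought responses in the limma test of the difference, while 885 had an unadjusted p under 0.05 and 782.3 are expected by chance. Without Col-0 drought replicate 1, 37 probe sets were called, among them DFR at -6.06 (adjusted p = 0.0187), AT2G45180 at 1.79 (adjusted p = 0.0242) and AT1G53560 at 1.33 (adjusted p = 0.0441). Besides AT1G53560, the genes with the smallest p were DFR at -5.27 ± 1.02 (adjusted p = 0.472), AT5G24570 at 1.43 ± 0.28, AT2G45180 at 1.56 ± 0.31 and AT5G52050 at 2.54 ± 0.55. For DFR the genotypes differed by -4.13 in drought, so part of the -5.27 came from the watered arrays. There Col-0 was near the floor, at 4.52 ± 1.86 (SD, n = 3). CAMTA5 was at 0.31 ± 0.31 in the difference of the responses. The flavonoid list was shifted, its response being lower in camta5 by a median of 2.82 (directional test of the list, adjusted p = 9.89e-06, and adjusted p = 0.120 with an estimated correlation), and fry, which tests the list without setting it against other genes, gave an adjusted p of 0.0896. The list's median was -1.85 without Col-0 drought replicate 3. Of its 4 genes, 3 were called lower adjusted over the list alone, and none over all probe sets. The other 5 lists were not shifted, with adjusted p of 0.313 or more.

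With water, camta5 and Col-0 plants did not differ at any single probe set in limma. At an unadjusted p under 0.05 there were 1000 probe sets, against 782.3 expected by chance. The 5 genes with the smallest p had adjusted p of 0.117 to 0.157. AT5G14120 was at 6002 ± 1057 in camta5 and 2685 ± 490 in Col-0 (n = 3 each), AT5G66590 at 1186 and 603.5, AT4G10925 at 1052 and 560.9, AT1G74940 at 621.9 and 304.3, and AT3G02840 at 184.7 in camta5 and 847 ± 404 in Col-0. None of the 6 lists was shifted, with adjusted p of 0.290 or more, while the senescence list had an adjusted p of 0.0386 without Col-0 water replicate 1. In a fit of these 6 arrays alone 44 probe sets were called, among them AT5G14120, AT5G66590 and AT3G02840, with array weights 6, among them these 3 genes and AT4G10925, and without Col-0 water replicate 3 there were 4.

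After drought, anthocyanin genes were lower in camta5 than in Col-0. DFR differed by -4.13 ± 0.72 on the log2 scale (adjusted p = 0.0107), at 47.5 ± 2.14 against 2307 ± 3169 (SD, n = 3 each). UGT75C1 (AT4G14090), an anthocyanin glucosyltransferase, differed by -3.39 ± 0.67 (40.3 ± 25.1 against 845 ± 1008) and UF3GT was at 28.1 ± 12.0 against 540 ± 658 (adjusted p = 0.0342). For each of these 3 genes every camta5 array lay below every Col-0 array, which the naming rule required of DFR and UF3GT. Of 15646 probe sets, 2818 did not overlap between these groups, in either direction. For all 3 genes Col-0 drought replicate 3 was the highest of the Col-0 arrays. Without that array DFR differed by -2.92 (adjusted p = 0.0162), and the calls of UF3GT (-2.02, adjusted p = 0.148) and UGT75C1 (-2.43, adjusted p = 0.0691) ended. DFR differed by -4.92 and UF3GT by -3.59 without Col-0 drought replicate 1, both called. With an offset of 1 UF3GT (adjusted p = 0.0839) and UGT75C1 (0.0565) were not called, nor was UF3GT with moderation without trend (0.051). The UF3GT call also ended without Col-0 water replicate 2 (0.0527) or camta5 drought replicate 1, 2 or 3 (0.0624, 0.0574 and 0.132), and that of UGT75C1 without camta5 drought replicate 3 (0.094). In a fit of these 6 arrays alone none of the 3 was called, with adjusted p of 0.162 for DFR, 0.218 for UF3GT and 0.176 for UGT75C1. Genes higher in camta5 included AKINBETA1 (AT5G21170, a subunit of the SnRK1 energy-sensing kinase) at 1468 ± 218 against 418 ± 83.8, with a log2 difference of 1.78 ± 0.18 (adjusted p = 0.000387), and the auxin-conjugating genes IAGLU (AT4G15550) and WES1 (AT4G27260) with 1.44 ± 0.31 and 1.40 ± 0.22.

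In drought, 159 probe sets were higher and 69 lower in camta5. Higher were also M10 (AT2G41280, 2.18 ± 0.41), NAMT1 (AT5G04370, a nicotinate methyltransferase, 1.66 ± 0.30), the trihelix factor gene GT2 (AT1G76890, 1.04 ± 0.22), UGT74B1 (AT1G24100, of glucosinolate synthesis, 1.02 ± 0.19) and TBL25 (AT1G01430, 0.97 ± 0.17). Lower were the chitinase gene CHI (AT2G43570, -1.90 ± 0.43), the vacuolar processing enzyme gene BETA-VPE (AT1G62710, -1.62 ± 0.29), SWEET4 (-1.47 ± 0.31), IQD30 (AT1G18840, a calmodulin-binding protein, -1.44 ± 0.29) and the pectin methylesterase gene PMEPCRF (AT5G53370, -0.74 ± 0.15). Of the 4 flavonoid genes 3 were lower (4 adjusted over the list alone), with a median of -3.19 (adjusted p = 2.75e-06, and adjusted p = 0.0940 with an estimated correlation). Without Col-0 drought replicate 3 the median was -2.23, and the list was called with an estimated correlation too (adjusted p = 0.00696). The other 5 lists were not shifted, with adjusted p of 0.478 or more, while the dehydration list had an adjusted p of 0.00664 without Col-0 drought replicate 2. Without Col-0 drought replicate 3, M10 (adjusted p = 0.0674), IAGLU (0.162), GT2 (0.0828), UGT74B1 (0.0573), TBL25 (0.0552), CHI (0.19), BETA-VPE (0.0665), SWEET4 (0.149), IQD30 (0.149) and PMEPCRF (0.129) were not called, and without camta5 drought replicate 3 the same genes except for TBL25 and CHI were not called (0.0505 to 0.115). Without Col-0 drought replicate 2, M10 (0.0524), IAGLU (0.0962), GT2 (0.0669), UGT74B1 (0.0549), CHI (0.118), SWEET4 (0.0931), IQD30 (0.089) and PMEPCRF (0.0507) were not called. GT2, CHI and SWEET4 were not called without camta5 drought replicate 1, and IAGLU, CHI and PMEPCRF not without camta5 drought replicate 2, with adjusted p of 0.050 to 0.113. Through the shared spread, the CHI call also ended without any 1 of the Col-0 water arrays, camta5 water replicate 1 or either OX5 array (0.0567 to 0.0671), that of IAGLU without Col-0 water replicate 2 (0.0516) or camta5 water replicate 1 (0.0535), and that of GT2 without camta5 water replicate 1 (0.0521). An offset of 1 ended the calls of NAMT1 (0.13) and CHI (0.0604), moderation without trend those of IAGLU (0.0679), GT2 (0.0543), CHI (0.0887), SWEET4 (0.0601) and PMEPCRF (0.055), and robust moderation (0.0675) or no OX5 arrays (0.0571) that of CHI. With camta5 water replicate 1 counted as Col-0, GT2 (0.0508), CHI (0.0725) and SWEET4 (0.0578) were not called. AKINBETA1, NAMT1, WES1 and DFR were called whichever 1 array was left out, and in a fit of these 6 arrays alone AKINBETA1 was the only gene named here still called. The 159 higher and 69 lower probe sets were 335 and 217 without Col-0 drought replicate 1, 66 and 18 without Col-0 drought replicate 3 and 258 and 169 with array weights. In a fit of these 6 arrays alone 9 were higher and 0 lower. The lower ones were 22 without camta5 drought replicate 3, where 130 were called in all, 37 with moderation without trend and 44 without camta5 water replicate 1.

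**Figure D2:**
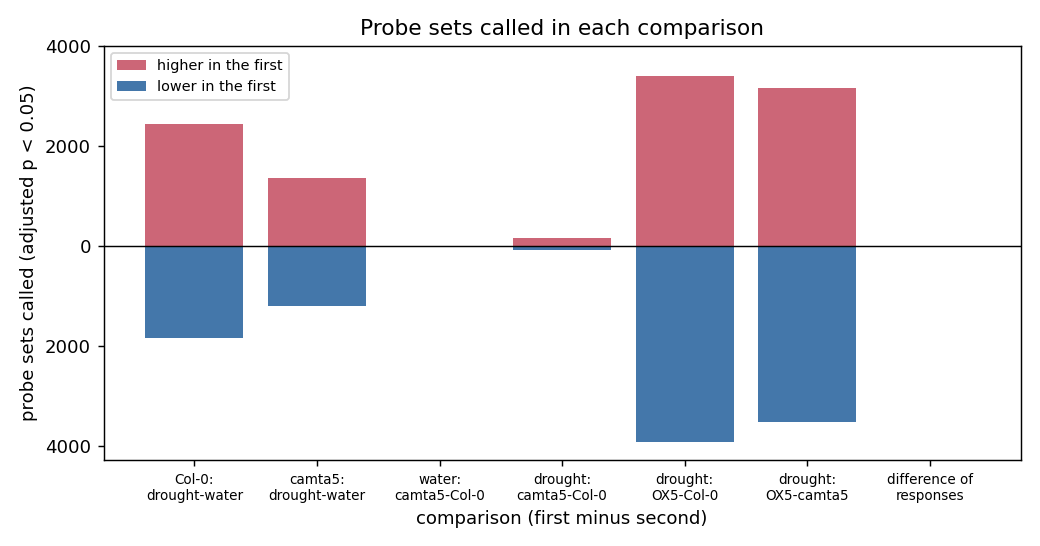
Probe sets called in each comparison (adjusted p under 0.05), with counts higher in the first group above 0 and lower below 0. OX5 against Col-0 in drought had 3395 higher and 3913 lower, and camta5 against Col-0 in drought 159 and 69.

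**Figure D3:**
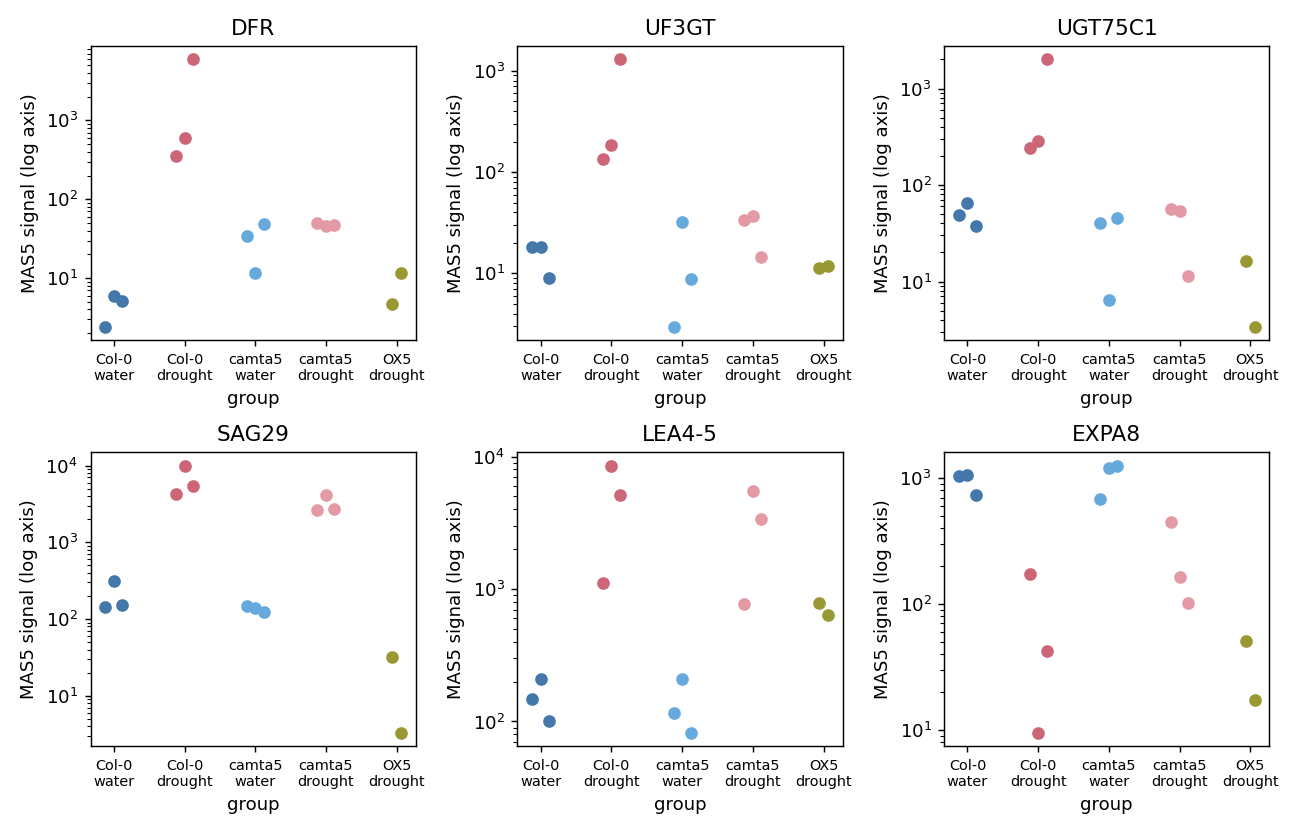
MAS5 signal on a log axis for DFR, UF3GT, UGT75C1, SAG29, LEA4-5 and EXPA8 in the 5 groups, 1 point per array. DFR was 352 to 5963 in the 3 Col-0 drought arrays and 45.4 to 49.7 in the 3 camta5 drought arrays.

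The OX5 arrays in drought differed from the Col-0 drought arrays at 7308 of 15646 probe sets. Both OX5 arrays also stood apart in control signals given below, so a labelling or hybridisation batch cannot be told apart from the line. CCOAMT (AT1G67980), a methyltransferase gene of phenylpropanoid metabolism, was at 10268 ± 1075 (SD, n = 2) against 24.8 ± 2.61 (n = 3), with a log2 difference of 7.98 ± 0.35. The auxin-conjugating enzyme gene GH3.3 (AT2G23170) was 6.69 ± 0.46 higher, the osmotin gene OSM34 (AT4G11650) 6.17 ± 0.62 and the defensin genes PDF1.2b and PDF1.2 (AT5G44420) 6.09 ± 0.87 and 5.56 ± 0.69. SAG29 differed by -7.66 ± 0.41, DI21 by -5.19 ± 0.71, BETA-VPE by -4.91 ± 0.33 and DFR by -5.54 ± 0.81, with DFR at 8.20 ± 4.90 (n = 2) in OX5. Leaving out Col-0 drought replicate 1 gave differences of -6.33 for DFR and -6.02 for DI21, without replicate 2 that of DI21 was -4.26, without replicate 3 that of DFR was -4.32, and without OX5 replicate 1 or 2 that of SAG29 was -8.32 or -7.00, all called. The OX5 arrays lay above all 12 others in the bioB spike-in control (851 and 561 against 29.0 to 127), within their range in the cre spike-in (22852 and 18894 against 13673 to 26757 for 1 of its probe sets), and below them in the 25S rRNA signal (4383 and 5961 against 8274 to 16184). The ratios of 3' to 5' signal, a measure of RNA integrity and labelling, were also lower on the OX5 arrays for actin (3.62 and 3.19 against 6.22 to 14.6) and GAPDH (1.116 and 0.980 against 1.123 to 1.71), and for ubiquitin were 1.08 and 0.795 against 1.07 to 1.51.

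OX5 had 3395 probe sets higher and 3913 lower than Col-0 in drought. Further large rises were GAT1_2.1 (AT1G15040, 6.25 ± 0.48), EXO (AT4G08950, 5.44 ± 0.47) and the cold-regulated gene COR27 (AT5G42900, 5.29 ± 0.43), and further large falls AFR (AT2G24540, -5.54 ± 0.34), the trichome regulator gene GIS (AT3G58070, -5.49 ± 0.29), SNZ (AT2G39250, -4.51 ± 0.35) and IQD30 (-4.50 ± 0.33). All 4 flavonoid genes were lower, 4 also adjusted over the list alone, UGT75C1 by -4.43 ± 0.75, with a list median of -4.16 (adjusted p = 0.00588, and adjusted p = 0.505 with an estimated correlation). Of 6 dehydration genes 3 were higher, COR15B by 2.79 ± 0.29, and 1 lower, LEA4-5 by -2.35 ± 0.77. Among cell wall genes XTH16 (2.29 ± 0.54) and XTH18 (1.43 ± 0.53) were higher of 7, with 1 called adjusted over the list alone. Photosynthesis genes went both ways, with SBPASE (AT3G55800, a Calvin cycle phosphatase) at -2.03 ± 0.17 and PSBY at 1.14 ± 0.26. WRKY6 (AT1G62300) was 2.54 ± 0.43 higher and CAMTA6 -0.95 ± 0.21 in difference. These 5 lists were not shifted, with adjusted p of 0.327 or more. The LEA4-5 call ended without Col-0 drought replicate 2 or 3 or either OX5 array (adjusted p up to 0.10), and that of XTH18 without any 1 of the Col-0 drought arrays or without OX5 replicate 2 (up to 0.233). XTH18 was also not called with an offset of 64, array weights, quantile normalization, centring on the median or only the compared arrays (0.0571 to 0.128). LEA4-5 was at -3.21 without Col-0 drought replicate 1 and at -1.74 without replicate 2, XTH16 at 1.64 without replicate 2, and without replicate 3 UGT75C1 was at -3.47 and the flavonoid list had a median of -3.56. With each array centred on its median, which moved the median of all probe sets from -0.04 to -0.17, 2838 were higher and 4516 lower.

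The comparison of OX5 with camta5 in drought used the same OX5 arrays, with their higher bioB signal and lower 25S rRNA signal and actin and GAPDH ratios. CCOAMT was 7.31 ± 0.35 higher in OX5 (10268 ± 1075, n = 2, against 51.4 ± 24.1, n = 3), OSM34 6.70 ± 0.62, GH3.3 6.41 ± 0.46, GAT1_2.1 6.35 ± 0.48, CHI 5.23 ± 0.48, PDF1.2 5.16 ± 0.69, MSRB9 (AT4G21850) 5.15 ± 0.57 and PDF1.4 (AT1G19610) 4.69 ± 0.34. SAG29 (-6.67 ± 0.41), AFR (-5.34 ± 0.34), GIS (-5.01 ± 0.29) and DI21 (-3.92 ± 0.71) were lower, as were the plastid genes petL, rpoC1, ycf4 and atpF by 3.99 ± 0.64, 3.97 ± 0.29, 3.86 ± 0.55 and 3.77 ± 0.52. In this comparison 3153 probe sets were higher and 3513 lower, and 2485 and 4194 with each array centred on its median. None of the 6 lists was shifted, with adjusted p of 0.480 or more, and 1 of 4 flavonoid genes was lower. Called members were UGT78D2 (AT5G17050, a flavonoid glucosyltransferase, -3.23 ± 0.27), XTH16 (251 ± 74.0 against 42.2 ± 31.9), EXPA8 (-2.18 ± 0.67), COR15B (2.65 ± 0.29), COR47 (AT1G20440, a dehydrin, 0.91 ± 0.33), CAMTA6 (-0.98 ± 0.21), WRKY6 (2.02 ± 0.43), SBPASE (-1.91 ± 0.17) and LHCB4.1 (AT5G01530, 1.04 ± 0.17). The EXPA8 call ended without camta5 drought replicate 1 (adjusted p = 0.0655) or OX5 replicate 2 (0.139), and that of COR47 without camta5 drought replicate 1 (0.059) or 2 (0.106), camta5 water replicate 1 (0.050) or either OX5 array (0.183 and 0.0811). COR47 was also not called with no filter, quantile normalization, centring on the median, moderation without trend or array weights (0.0515 to 0.215). Without OX5 replicate 1 or 2 the SAG29 difference was -7.33 or -6.01, and without camta5 drought replicate 1 those of petL, ycf4 and atpF were -2.97, -3.02 and -2.97, all called.

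The camta5 and OX5 differences from Col-0 in drought share the Col-0 drought arrays. Across probe sets their r was 0.42, and simulated unchanged groups with the same controls gave 0.443. The covariance was 0.264 against 0.0496 in the simulation, a difference of 0.215. Both called 123 probe sets higher, against 34.5 from independent lists, and 48 lower, against 17.26. The expected counts ignore the shared arrays, and splitting 3 control arrays would leave fewer than 2 in a part. Some of this overlap may thus come from the shared controls. The simulated noise had the same spread in every group, so the covariance difference does not separate a shared effect from the shared controls either. For OX5 against Col-0 in drought, that difference was -0.214 with the Col-0 drought response, which shares arrays. With the camta5 drought response, which shares none, it was -0.0865.

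Besides the reference genes, 10 fixed lists had 1 or 2 measured members, 15 genes in all. In Col-0, drought raised THI2.1 and PYK10 and lowered STZ, PDF1.2, CHLM, PORB, GI, BCAT4, UGT74B1 and TRY. In camta5 it raised DELTA-OAT and PYK10 and lowered PDF1.2, CHLM, GI and BCAT4. OX5 was higher than Col-0 in drought at GRX480, PDF1.2, DELTA-OAT, CHLM, PORB and GI, and higher than camta5 at GRX480, PDF1.2, PORB and GI and lower at UGT74B1 and TRY. Both measured reference genes, SAND and TIP41, were called in no comparison.

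**Figure D4:**
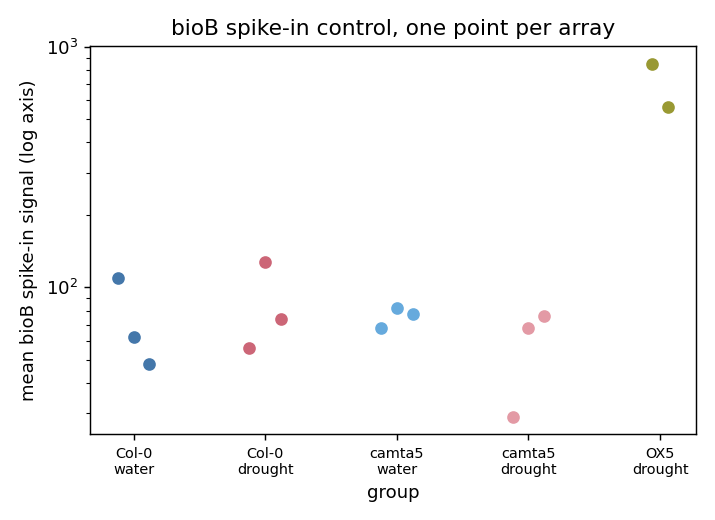
Mean signal of the 3 bioB spike-in probe sets on a log axis, 1 point per array. The OX5 arrays had 851 and 561, and the other 12 arrays lay between 29.0 and 127.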

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

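The tests of families, with each array left out too, of OX5 against watered Col-0, of the spike-ins, the slope, the within-group spread and the mutant label, and those of the anthocyanin list with an estimated correlation or fry on fewer arrays or after scaling, were chosen after the results were seen, and the others below before.

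For 1 fixed list and 3 later families a test of the difference between the drought responses of camta5 and Col-0 was past the threshold with all arrays. Flavonoid and anthocyanin genes had a median difference of -2.82 (-1.85 without Col-0 drought replicate 3), calmodulin-like proteins 0.78 (adjusted p = 0.00543), chloroplast-encoded transcripts 0.38 (adjusted p = 1.01e-05) and mitochondrion-encoded transcripts 0.27 (adjusted p = 0.0194). With an estimated correlation none of the 4 was called, with adjusted p of 0.120, 0.399, 0.627 and 0.601. Without camta5 drought replicate 1, on which petG was at 5863 against 382.6 and 228.2 on the other camta5 drought arrays, the chloroplast median was 0.00122 (adjusted p = 0.799) and the mitochondrial 0.071 (adjusted p = 0.435). The mitochondrial call also ended without Col-0 water replicate 1 (0.228), Col-0 drought replicate 2 (0.131) or camta5 water replicate 3 (0.0567). The bioB spike-in, a control transcript that is no part of the comparisons, had a signal of 851.1 and 561.3 on the OX5 arrays against 29.0 to 127 on the other 12. The cre spike-in of both OX5 arrays lay within the range of the others (22852 and 18894 against 13673 to 26757 for 1 of its probe sets), and for bioC and bioD OX5 replicate 1 lay above that range and replicate 2 within it (8152 and 5969 against 3437 to 6920 for bioD).

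For the anthocyanin genes, which were lower in camta5 than in Col-0 in drought, 1 array as the sole cause is argued against, since without any 1 array the list had an adjusted p of at most 3.49e-05 with the preset correlation and at most 0.0387 by fry. With an estimated correlation the list was not called with all arrays (adjusted p = 0.0940) or without any 1 array (0.0730 to 0.184) except Col-0 drought replicate 3, without which the adjusted p was 0.00696, the correlation 0.0422 in place of 0.657 and the median -2.23 in place of -3.19. A milder response of camta5 at all genes alike stays open, as does variation between plants of 1 group: after the Col-0 response was scaled by the overall slope of 0.78 the list had a median of -2.12, with adjusted p of 1.77e-05 with the preset correlation, 0.134 with an estimated correlation and 0.161 by fry. Among single genes, UF3GT and UGT75C1 lost their calls without Col-0 drought replicate 3 (adjusted p = 0.148 and 0.0691) or camta5 drought replicate 3 (0.132 and 0.094), and UF3GT also without Col-0 water replicate 2 (0.0527) or camta5 drought replicate 1 or 2 (0.0624 and 0.0574). The SD of DFR among the Col-0 drought arrays was 1.40 times the difference between the groups on the linear scale and 0.517 times on the log2 scale, so an effect of genotype remains an untested hypothesis beside it.

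For the OX5 arrays, which differed from Col-0 in drought at 7308 probe sets, a milder drought state is argued against as the whole cause, since OX5 differed from watered Col-0 at 8286. The authors' scaling is argued against likewise, with 7569 calls after quantile normalization. A labelling or hybridisation batch and the transgene, which was not tested, cannot be told apart, because such a batch would hold both OX5 arrays and no other: the lowest OX5 signal of bioB was 4.41 times the highest of the other arrays, while cre did not set them apart. Whether the OX5 differences ran against the drought response was left undecided for such a batch: r with the camta5 response was -0.098 and the bound set beforehand was -0.1. For a milder drought state, the medians of OX5 minus Col-0 in drought missed the bounds set beforehand. They were -0.085 for the set raised by drought in camta5 and -0.024 for the lowered set. Against watered Col-0 these sets had medians of 0.84 and -1.05 in OX5, beside 0.88 and -0.98 in Col-0 in drought. At their medians, the sets thus showed no milder drought state. Their members went both ways (53.1% and 51.0% below Col-0), with SDs of 1.41 and 1.61, so this does not extend to single genes.

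For CAMTA5, not lower in the camta5 arrays, the array with the wild-type genotype entry is argued against as the sole cause. The lowest of the other camta5 water arrays was at 153.8, above the lowest Col-0 water array at 114.7. A probe set outside the lesion and a wrong label of the line stay open. Between camta5 and Col-0 no probe set was called with water and 228 were in drought. The camta5 and Col-0 water arrays correlated at 0.943 to 0.960, beside 0.947 to 0.954 within Col-0 water. A wrong label could leave such values with water, but so could a mutation of little effect, so they do not decide it.

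The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. Drought against water gave 4277 calls in Col-0 and 2547 in camta5, and the highest other splits gave 0 and 3. For camta5 against Col-0 the real counts were 0 with water and 228 in drought, and the highest other splits gave 1 and 131. For the difference of the drought responses the real count was 0, so that 100 of 100 drawn splits reached it by construction and say nothing about chance. Of these splits 9 gave any call and the highest gave 79, and whether a structure of the samples other than genotype lay behind that was not tested. Both that split and the one with 131 calls put Col-0 drought replicate 1 with camta5 drought replicates 1 and 3.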

How the results depend on the processing

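The fit without the OX5 arrays was chosen after seeing the data. It called 4549, 2694 and 213 probe sets for drought in Col-0, drought in camta5 and camta5 against Col-0 in drought, of which 4199, 2465 and 194 were shared with the counts of 4277, 2547 and 228, and 0 for the other 2 comparisons without OX5 (1106 and 951 at an unadjusted p under 0.05). No called gene or list changed sign in 3032 values under the alternatives. Many alternatives leave the log2 difference itself unchanged, and the largest rises and falls were chosen for arrays that did not overlap. A change of sign was thus largely excluded beforehand. The balance of the drought calls in camta5 turned from more higher to more lower with quantile normalization (1109 and 1183) and centring on the median (1189 and 1310). Among values of named genes other than CAMTA5 under the alternatives, 2923 kept their direction and side of the threshold, 141 lost the call and 10 gained it, and for CAMTA5 170 values kept both and 17 lost the call. Low signal limits the fold changes of genes near the offset. The cause of the changes below was not tested, except that stricter thresholds give fewer calls by construction.

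An adjusted p under 0.01 left 2227 probe sets for drought in Col-0, 838 for drought in camta5 and 63 for camta5 against Col-0 in drought. A change of at least 2-fold left 1945 for drought in Col-0 (896 higher and 1049 lower) and 1090 for drought in camta5 (494 and 596), so that more were lower in both. It left 4805 and 4212 for OX5 against Col-0 and camta5. For camta5 against Col-0 in drought, moderation without trend gave 144, array weights 427 and only the compared arrays 9. With water, array weights gave 6 and only the compared arrays 44. Counting camta5 water replicate 1 as Col-0 water left 1445 for drought in camta5. Leaving out 1 array gave 2601 to 4530 for drought in Col-0, 1121 to 2920 for drought in camta5, 84 to 552 for camta5 against Col-0 in drought, 0 to 4 with water and 0 to 37 for the difference of the responses.

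For CAMTA5 the drought difference in camta5, 0.68 before, lost its call with an offset of 1 (0.73), no filter (0.68), quantile normalization (0.62) and the other grouping of camta5 water replicate 1 (0.75), and ranged from 0.61 to 0.75 with 1 array left out. For OX5 against Col-0 it lost the call with only the compared arrays (0.76) and ranged from 0.54 to 0.99.

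Of the 6 fixed lists, an estimated correlation left 1 shifted for drought in Col-0 and 0 for drought in camta5, camta5 against Col-0 in drought, OX5 against Col-0 and the difference of the responses. By fry, which does not set a list against other genes, 5 and 4 moved for drought in Col-0 and camta5, 3 each for OX5 against Col-0 and camta5, and 0 for the difference. Quantile normalization left 1 for drought in camta5. With 1 array left out, 0 to 1 were shifted for camta5 against Col-0 with water and 1 to 2 in drought. Without a filter the correlation of the drought responses was 0.69.

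With the replicate number as a block, the CAMTA5 drought difference in camta5 stayed at 0.68 with an adjusted p of 0.0665, and that of CAMTA6 at 0.60 lost its call too (0.0589). Deviations of 26 pairs of arrays with the same number correlated at -0.164 to 0.235, and 3 pairs exceeded 0.1. Col-0 drought with camta5 drought gave the highest values, 0.228 for replicate 1 and 0.235 for replicate 2, but -0.159 for replicate 3. Pairs with different numbers were not examined, so whether the numbers pair the samples stays undecided.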

Other observations

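The tests of families, with each array left out too, and the comparison with watered Col-0 were chosen after the annotation or the data were seen. Part of the transcripts encoded in the chloroplast genome fell after drought. In Col-0, 39 of 69 were lower, 0 higher (1 without Col-0 water replicate 1) and 30 not called, with a median of -0.94 (adjusted p = 3.36e-16, and adjusted p = 0.311 with an estimated correlation), petG by 3.54 ± 0.78 and psbB by 3.36. In camta5, 16 were lower, 1 higher and 52 not called (lower and higher 9 and 0 after quantile normalization), with a median of -0.63 (adjusted p = 3.69e-11, and adjusted p = 0.503 with an estimated correlation). The 16 were 43 without camta5 drought replicate 1, on which petG was at 5863 against 382.6 and 228.2 on the other camta5 drought arrays, and 2 to 6 without any 1 of the other camta5 arrays, and the 1 higher was not called without any 1 of the camta5 or Col-0 drought arrays or Col-0 water replicate 3. OX5 in drought was lower than Col-0 in drought at 34 of the 69 and higher at 2, or 0 without OX5 replicate 1 and 1 without Col-0 drought replicate 3 (median -1.02, adjusted p = 9.92e-05, and adjusted p = 0.742 with an estimated correlation), with rpoC1 differing by -3.50, on arrays whose 25S rRNA signal was also lower (4383 and 5961 against 8274 to 16184 on the other 12). No median of these transcripts changed sign with quantile normalization or centring on the median in these 3 comparisons. Nuclear-encoded thylakoid genes were lower after drought in Col-0 at 4 of 10 (9 without Col-0 drought replicate 1 and 7 without camta5 drought replicate 1), with a median of -0.70 (adjusted p = 0.000134, and adjusted p = 0.311 with an estimated correlation).

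Beta-glucosidase genes were higher in OX5 than in Col-0 in drought at 5 of 9 and lower at 2 (0 without OX5 replicate 1, and 1 without OX5 replicate 2, Col-0 drought replicate 1 or 3, camta5 water replicate 1 or any 1 of the Col-0 water arrays), with a median of 2.98 (adjusted p = 0.0296, and adjusted p = 0.398 with an estimated correlation). BGLU16 differed by 4.36 and BGLU46 by 4.14. Tau-class glutathione transferase genes were lower in OX5 than in camta5 at 5 of 7, with a median of -1.31 (adjusted p = 0.0457, and adjusted p = 0.275 with an estimated correlation). That call ended without camta5 drought replicate 1 (0.0551) or 3 (0.0682) or OX5 replicate 2 (0.133, with 3 lower). Against both Col-0 groups in 1 direction, OX5 differed at 5497 probe sets, 2610 higher and 2887 lower. HYH (AT3G17609), a light-signalling transcription factor gene, was at 65.8 in OX5, 957 in Col-0 in drought and 1996 in Col-0 with water, and SWEET13 (AT5G50800) at 39.7, 578 and 691. BZIP61 (AT3G58120) was at 510 in OX5, 7.55 in Col-0 in drought and 14.0 in Col-0 with water. These 3 genes were chosen after their values were seen.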
